A study of Mus musculus with 6 samples.

How the data were processed

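Total RNA of 6 samples of mouse bone marrow cells, cultured with interleukin-7, had been biotin-labelled and hybridised to 6 oligonucleotide arrays, 3 of cells lacking Cry1 and Cry2 and 3 of wild type cells, all of strain C57BL/6 per the labels. The deposited values are intensity on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes, which give no version. In the deposited table the mean signal without the highest and lowest 2% of values was 500 on every array, so each array had been scaled to a common target. Detection calls, the genome build and the array's hybridisation batches are not given in the sources used here. Groups were taken from the sample labels. The labels do not say whether arrays of 1 group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

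The table held 45101 probe sets, of which 64 controls were used only for quality. Of the other 45037, 34945 were listed with 1 gene symbol, 932 with several and 9160 with none, and only the first kind was named. Symbols were checked through gene identifiers against the gene table of assembly GRCm38.p6, where 34741 matched, and 204 kept the symbol as listed. Chromosome names and the order of genes were taken from the same table, with no coordinates used in the text. Genes on the lists without a named probe set are not analysed here.

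Values were transformed as log2(intensity + 16), so a log2 difference understates the change of dim genes. Array medians differed by 1.13, over the limit of 0.5 that had been set for centring, and each array was therefore centred on its median. Probe sets with a mean above percentile 40 were tested, 27022 in all. Linear models with group as the single term were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend in mean signal, two-sided, and p was adjusted by the Benjamini-Hochberg method over all tested probe sets at a threshold of 0.05. Genes were counted by the probe set with 1 symbol and the highest mean signal, 12627 tested. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over 21 lists. Each list was also tested with an estimated correlation, on ranks and with fry, which asks whether a list's genes move one way and makes no comparison with other genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

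The grouping, the fits, the filter, the pseudocount, the rule for centring, the other settings listed next, the 21 gene lists and the rule for named genes were fixed before the data were examined. The lists covered clock genes with E-boxes, RORE and other clock genes, complement and its receptors, pro-B and pre-B cell genes, immature and mature B cell genes, B cell receptor signalling, interleukin-7 receptor and STAT5 genes, apoptotic cell clearance, proliferation, p53 targets, interferon-stimulated, inflammatory and NF-kB, immediate early and heat shock genes, and sex-linked genes. The other 7 lists held markers of macrophages and monocytes, granulocytes, T, NK and innate lymphoid cells, dendritic cells, mast cells and basophils, erythroid cells and megakaryocytes, and stromal and endothelial cells. The rule named all probe sets of Cry1 and Cry2, and genes past the threshold whose groups do not overlap. Where fewer than 5 genes passed in a direction, it named those that passed and the ones with the smallest unadjusted p, up to 8, as values. It named the tested clock genes and the C1q genes, and for each further list the called members, up to 4, or the 2 with the smallest p.

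These settings were quantile normalization, centring over the tested probe sets, pseudocounts of 1 and 64, no filter, a filter at percentile 60, variances without trend or robust to outliers, array weights, each array left out in turn, the replicate number as a block, other rules for the probe set of a gene, a log2 difference of at least 1, and the other list tests. After seeing the data, fits without WT 2 were added with quantile normalization, with each other array left out as well, and with the other list tests, an estimated correlation without DKO 1, DKO 2 or DKO 3 was added, and a fit of the values as deposited without centring.

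The fit was tested on simulated data for DKO against WT over 27022 probe sets, with 50 changed at each size. With equal spread on all 6 arrays, 32% of log2 changes of 1, 72% of 2, 92% of 4 and 96% of 8 were recovered, with 11 false calls. With the extra spread of WT 2, these shares were 0%, 6%, 64% and 96% with 0 false calls, and 10%, 50%, 84% and 96% with 3 false calls when WT 2 was left out. Whether the 100 genes with the smallest p, each gene here taken by the probe set with its smallest p and not by the one with the highest signal, lie near each other on chromosomes was asked after seeing the data. The first statistic, the number of these genes with another of them within 25 genes, did not recover a simulated stretch (permutation p = 0.32) and had by then also been computed on the arrays. It was replaced by the number of pairs within 25 genes, which recovered the simulated stretch at the smallest p that 2000 permutations can give and gave a permutation p of 0.474 for random genes. The simulated genes lay closer together than those found on chromosome 14, so this recovery does not show how the statistic fares on looser groups. Both statistics are reported.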

Results

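Gene expression was measured in cultured mouse bone marrow cells that lacked both cryptochromes, Cry1 and Cry2, and in wild type cells. Cryptochromes are the repressors that close the negative loop of the circadian clock, and interleukin-7, which the cultures received, sustains early B lymphocytes. There were 3 arrays per genotype, labelled DKO 1 to DKO 3 and WT 1 to WT 3, each an oligonucleotide array read as 1 signal per probe set. The number of arrays limits the precision of every comparison. The single comparison asked which genes differ between the genotypes.

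WT 2 differed from the other 5 arrays in the quality measures given here. The 3' to 5' signal ratio of the Actb control probe sets was 824 on WT 2 and 1.47 to 2.05 on the others, and that of Gapdh was 132 against 0.838 to 1.72. Bacterial control transcripts added before hybridisation were 4.52 times their mean on the other arrays, and the median signal was 115 against 44.0 to 55.3. Its correlation with the other arrays, across probe sets, was 0.752 to 0.780, and correlations among the other 5 ranged from 0.936, for DKO 1 with DKO 3, to 0.984, for DKO 3 with WT 3. DKO 3 correlated with WT 1 (0.968) and WT 3 more closely than with DKO 1 or DKO 2 (0.952). Gene values are from all 6 arrays unless stated. Of 75 named genes, 14 moved by over 1.5 times in fold without WT 2, a choice made after seeing the data, and their values without it are given too, as are list results whose call changed without it. Of 35 genes named by the fixed rule with over 1 tested probe set, 10 had probe sets of opposite sign with all 6 arrays, namely C1qb, Ret, Tef, Clock, Csnk1d, Timeless, Cd22, Ccnd2, Mcm5 and Rrm2. Without WT 2 only 2 of these 10, Tef and Clock, still did, and 5 of the 35 in all. Leaving out DKO 3 moved 16 named genes by over 1.5 times in fold, and leaving out DKO 1, DKO 2, WT 1 or WT 3 moved 6, 4, 6 and 6.

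**Figure D1:**
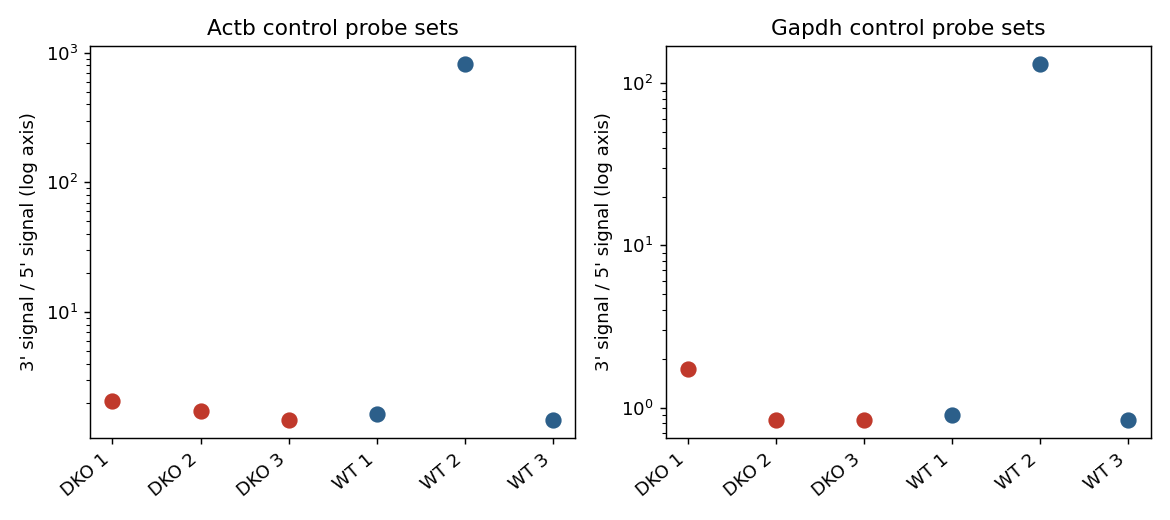
Ratio of 3' to 5' signal for the Actb and Gapdh control probe sets (vertical axes, logarithmic, no unit) on each of the 6 arrays (horizontal axes, DKO red, WT blue, 1 point per array). WT 2 lies at 824 for Actb and 132 for Gapdh, and no other array exceeds 2.05.

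Cry1 signal was lower in the knockout cells and Cry2 signal was not. The single Cry1 probe set read 359, 399 and 545 in DKO 1 to 3 and 1533, 1502 and 955 in WT 1 to 3. On the log2 scale this was 8.95 ± 0.44 (SD, n = 3) against 10.21 ± 0.47 (SD, n = 3), a difference of -1.26 with a standard error of 0.46 and a limma adjusted p of 0.822. The single Cry2 probe set was dim in both genotypes, at 162, 178 and 133 in DKO 1 to 3 and 145, 102 and 105 in WT 1 to 3, a difference of 0.70 with a standard error of 0.41 and a limma adjusted p of 0.822. Whether either probe set lies in the deleted part of its gene was not analysed here, so these signals do not test the labels.

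Probe sets of Igha, the constant region gene of the IgA heavy chain, read higher in the knockout cells, and Igha was the only gene named by the fixed rule that passed the threshold with all 6 arrays. Its representative probe set read 19431, 14896 and 6180 in DKO 1 to 3 and 30.7, 162 and 44.9 in WT 1 to 3. The log2 difference was 7.56 with a standard error of 0.53 and a limma adjusted p of 0.0435. On WT 1 and WT 3 the signal lay below the array median, so the size of the difference depends on the pseudocount and no fold is given. Another Igha probe set differed by 7.96 with a limma adjusted p of 0.049. A further Igha probe set differed by 6.27 with an adjusted p of 0.109. These 2 Igha probe sets were the only ones of 27022 that limma called, both higher in DKO, and 0 were lower. At an unadjusted p under 0.05, limma counted 490 higher and 354 lower, 844 in all, where 1351 were due by chance. More were lower with quantile normalization (384 higher, 469 lower), centring over the tested probe sets (318 and 482) and no centring (259 and 504). The same held without WT 2 (504 and 588). More stayed higher with the other pseudocounts and filters. The groups did not overlap in 2772 probe sets, 10.3%, where chance gives 10%. Leaving out any 1 of DKO 1, DKO 2, DKO 3, WT 1 and WT 3 gave 0 calls. Without WT 2 there were 5 calls, namely the same 2 of Igha, 1 of Ighm (5.74) and 1 each of Psmd6 (-3.83) and Adi1 (-3.04), the last 3 named after their values were seen. Other probe sets of these genes followed in part. In the same fit 4 other tested Ighm probe sets read 2.17 to 2.99 and 3 read -0.32 to -0.04, among the latter the 2 with the highest signal, the second Psmd6 probe set read -0.10, and the other Adi1 probe sets read -1.05 and 1.49. Whether sequence variants between mouse strains lie under the probes of Igha or of these genes was not analysed here, so a difference in probe binding is not separated from one in expression. Jchain, the immunoglobulin joining chain gene, also named after its values were seen, differed by 3.91 with a limma adjusted p of 0.428. It read 6321, 2655 and 1907 in DKO 1 to 3 and 314, 550 and 82.3 in WT 1 to 3. Whether Jchain shares a cause with Igha was not tested.

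The genes with the next smallest p, ranked by the representative probe set of each gene, did not pass the threshold. On the side of higher signal in DKO they were Gdpd3 (4.36), the clock genes Per2 (2.89) and Per3 (2.32), Ccn3 (3.27), Tnfrsf14 (3.12), Mxra8 (1.73) and Meak7 (1.88), with limma adjusted p from 0.109 to 0.428. On the side of lower signal they were Fhit (-2.06), 2010109A12Rik (-1.86), Ppp1r3e (-2.35), Ang (-2.19), Ret (-2.35), Gm26782 (-1.65), Cldn34c1 (-1.52) and Ahr (-1.65), the aryl hydrocarbon receptor, with limma adjusted p from 0.524 to 0.822. The other tested probe set of Ret read 0.04 and that of Ahr -0.10.

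Clock genes that are transcribed through E-boxes, the DNA elements on which cryptochromes repress CLOCK and BMAL1, were higher as a list in the knockout cells. Of 13 members tested, 11 had higher and 2 had lower mean signal in DKO, with a median log2 difference of 1.27 where the median of all tested probe sets was 0.21. The list passed camera with an adjusted p of 4.4e-06 over 21 lists, with an adjusted p of 0.365 with an estimated correlation and an adjusted p of 0.0312 by fry. Per2 differed by 2.89 with a standard error of 0.35, at 8.76 ± 0.24 (SD, n = 3) in DKO and 5.87 ± 0.47 (SD, n = 3) in WT. Per3 differed by 2.32 with a standard error of 0.31, and Tef, a PAR-domain transcription factor, by 2.25 with a standard error of 0.38. Nr1d1 and Nr1d2, which encode the REV-ERB repressors, differed by 2.91 and 3.08, with standard errors of 0.77 and 0.81. Bhlhe40 differed by 2.94, Per1 by 1.27, Dbp by 1.21 and Ciart by 0.72. With 1 array left out, Nr1d1 read 2.41 to 3.60 and Bhlhe40 2.07 to 3.74. Bhlhe40 on DKO 3 (7.62) lay below WT 1 (7.69). Without WT 2, Nr1d2 read 2.14, Bhlhe40 2.07, Per1 0.36 and Wee1 -0.25. Wee1 (0.38) and Usp2 (0.06) turned sign under quantile normalization (-0.09 and -0.35), and Hlf (-0.21) and Bhlhe41 (-0.54) were on the lower side. Adjustment over the members of a list alone was not among the fixed settings, and it is not corrected for the 21 lists. Adjusted in this way, 6 members passed, namely Per2, Per3, Tef, Nr1d1, Nr1d2 and Bhlhe40, and over all probe sets 0 did. The other tested probe set of Per2 read 0.54, those of Per3 read 0.40, 0.78 and 0.88, those of Tef read 1.42 and -0.37, that of Dbp 2.40 and that of Usp2 0.94. Nr1d2 lies on chromosome 14 within 25 genes of 3 others of the 100 genes with the smallest p. Tef, on chromosome 15, lies as near to 1 other of them, and Per2, Per3 and Nr1d1 to 0. Chromosome 4, which holds Per3, had 11 of the 100 where 6.12 were due. Without WT 2 the camera adjusted p was 3.1e-08, with an adjusted p of 0.658 with an estimated correlation and 0.0858 by fry, and 5 members passed when adjusted over the list alone, namely Per2, Per3, Tef, Nr1d2 and Dbp, with Nr1d1 (adjusted p = 0.0573) and Bhlhe40 (0.0939) no longer among them.

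**Figure D2:**
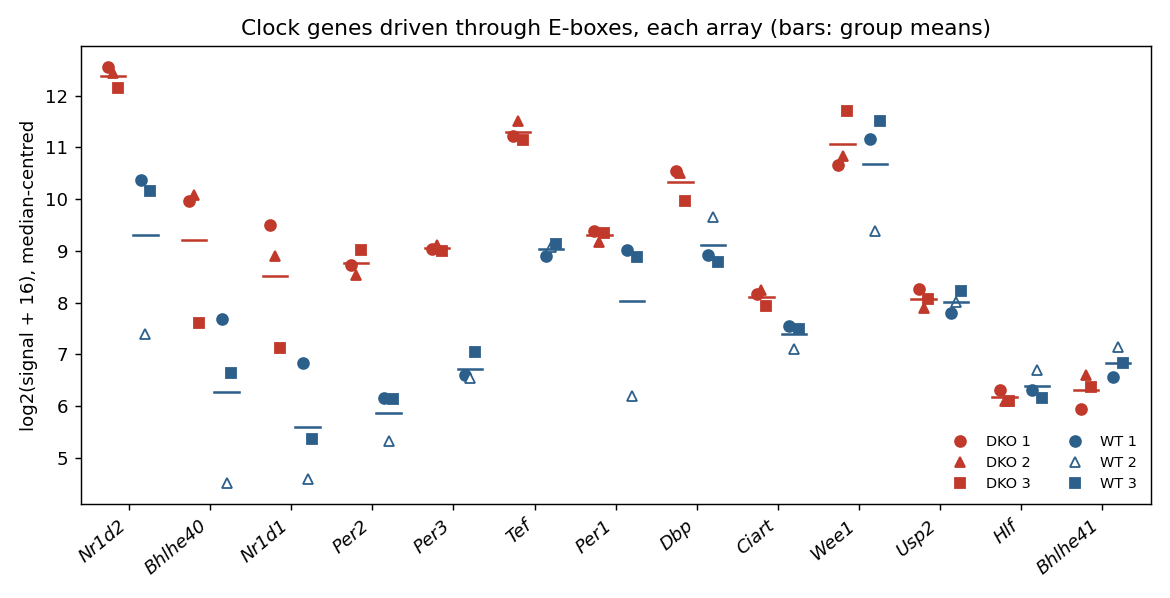
Level of the 13 tested clock genes of the E-box list (horizontal axis) as log2 signal with a pseudocount of 16, centred on each array's median (vertical axis). Points are single arrays (DKO red, WT blue, WT 2 open) and bars are group means. Per2, Per3 and Tef lie higher on each DKO array than on any WT array.

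The list of RORE and other clock genes, which is not defined by 1 shared element, showed no shift. Of 7 tested, 4 had higher and 3 had lower mean signal in DKO, and camera gave an adjusted p of 0.734, with 0 members passing when adjusted over the list alone and 0 over all probe sets. Arntl, which encodes BMAL1, differed by 1.08 with a standard error of 0.72. Clock differed by 1.19, Csnk1e by 0.69 and Timeless by 0.30, each of which had the opposite sign without WT 2 (-0.07, -0.34 and -0.35). Nfil3 differed by -0.27, Rora by -0.10 and Csnk1d by -0.41, the last 2 with the opposite sign without WT 2.

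Complement genes and their receptors were shifted to lower signal in DKO by camera (adjusted p = 0.0496), and this shift was lost in most other settings. Of 13 tested, 6 had higher and 7 had lower mean signal, with an adjusted p of 0.452 with an estimated correlation and an adjusted p of 0.398 without WT 2. It was 0.112 without DKO 1, 0.0663 without DKO 2 and 0.14 without WT 1. The median of the list, each gene against its mean over the 6 arrays, was -0.33 and -0.16 on DKO 1 and DKO 2 and 0.65 on DKO 3, above WT 1 to 3 (0.15, -0.35 and 0.28), so DKO 3 did not share the shift. No member passed over all probe sets or when adjusted over the list alone. The subunits of C1q, the recognition molecule of the classical pathway, read -1.74 with a standard error of 0.78 for C1qb, -0.49 with a standard error of 0.59 for C1qc and 0.73 with a standard error of 1.35 for C1qa. C1qa read -0.67 without WT 2, where its signal was 10.5. Other C1qb probe sets read -1.14 and 0.10. C5ar1 differed by -1.68 and C2 by 1.25 (0.61 without WT 2). Genes for the clearance of apoptotic cells shifted to lower signal too (adjusted p = 0.0411, and adjusted p = 0.763 with an estimated correlation), with 11 of 18 lower, Itgb3 at -1.38 and Abca1 at 1.93. Without WT 2 their adjusted p was 0.099, and it was 0.0906 without DKO 1, 0.0828 without DKO 2 and 0.277 without WT 1.

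Granulocyte and macrophage markers were lower in DKO as lists, with low values on DKO 1 and DKO 2 and not on DKO 3. All 16 tested granulocyte markers had lower mean signal in DKO, with a median log2 difference of -1.61, a camera adjusted p of 1.9e-16 and an adjusted p of 0.452 with an estimated correlation. Without WT 2 the camera adjusted p was 2.5e-08, with an adjusted p of 0.658 with an estimated correlation. S100a8 read 7.75, 7.75 and 13.66 on DKO 1 to 3 and 14.68, 15.71 and 13.29 on WT 1 to 3, a log2 difference of -4.84 (-4.25 without WT 2), and S100a9 had a log2 difference of -4.97 with a standard error of 1.63. The number of the 16 markers below every WT array was 16 in DKO 1, 15 in DKO 2 and 0 in DKO 3. Of 25 macrophage and monocyte markers, 22 had lower mean signal (camera adjusted p = 8.2e-09, and adjusted p = 0.484 with an estimated correlation), including Csf1r (-2.04, and -1.39 without WT 2) and Tyrobp (-1.97). The median of the macrophage markers, each taken against its mean over the 6 arrays, was -0.56 on DKO 1 and -0.83 on DKO 2, and it was 0.72 on DKO 3, between WT 1 (1.22) and WT 3 (0.02), with WT 2 at -0.13. Without WT 2 the camera adjusted p of the macrophage list was 1.7e-07, with an adjusted p of 0.658 with an estimated correlation. No marker of either list passed over all probe sets or when adjusted over the list alone.

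B lineage genes did not pass as lists in the main fit of all 6 arrays. With other settings of all 6 arrays, camera called pro-B and pre-B cell genes with quantile normalization (adjusted p = 0.0166). It called immature and mature B cell genes with a filter at percentile 60 (adjusted p = 0.0141) and with the replicate number as a block (0.0221). Of 23 pro-B and pre-B cell genes, 18 had higher and 5 had lower mean signal in DKO (camera adjusted p = 0.124, and 0.0112 without DKO 3, where it was 0.464 with an estimated correlation). Dntt, the terminal transferase of early lymphocytes, read 13.38, 13.40 and 10.41 on DKO 1 to 3 and 10.46, 10.95 and 9.26 on WT 1 to 3, and Blnk differed by 1.18. Of 22 genes of immature and mature B cells, 11 were on each side (camera adjusted p = 0.0692), with a median of 0.00 and a camera direction towards lower signal. Without DKO 3 the adjusted p was 0.000364, and 0.464 with an estimated correlation. Without WT 2, 16 of these 22 were lower and the adjusted p was 0.0268, with an adjusted p of 0.658 with an estimated correlation. Cd22, an inhibitory receptor, read 9.94, 10.55 and 12.85 on DKO 1 to 3 and 12.66, 12.70 and 12.84 on WT 1 to 3, and Irf8 differed by 1.51 (0.77 without WT 2). B cell receptor signalling genes had 21 of 29 on the higher side (adjusted p = 0.684), and 13 of 29 without WT 2, where the camera direction turned to lower signal (adjusted p = 0.398). Genes of the interleukin-7 receptor and STAT5 had 17 of 19 on the higher side (adjusted p = 0.164) and 13 of 19 without WT 2 (adjusted p = 0.65), with Mycn at 1.67 and Ccnd2 at -0.82. Mycn read 11.57, 11.84 and 9.73 on DKO 1 to 3 and 9.59, 8.73 and 9.79 on WT 1 to 3. In these 4 lists 0 genes passed over all probe sets and 0 when adjusted over the list alone.

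**Figure D3:**
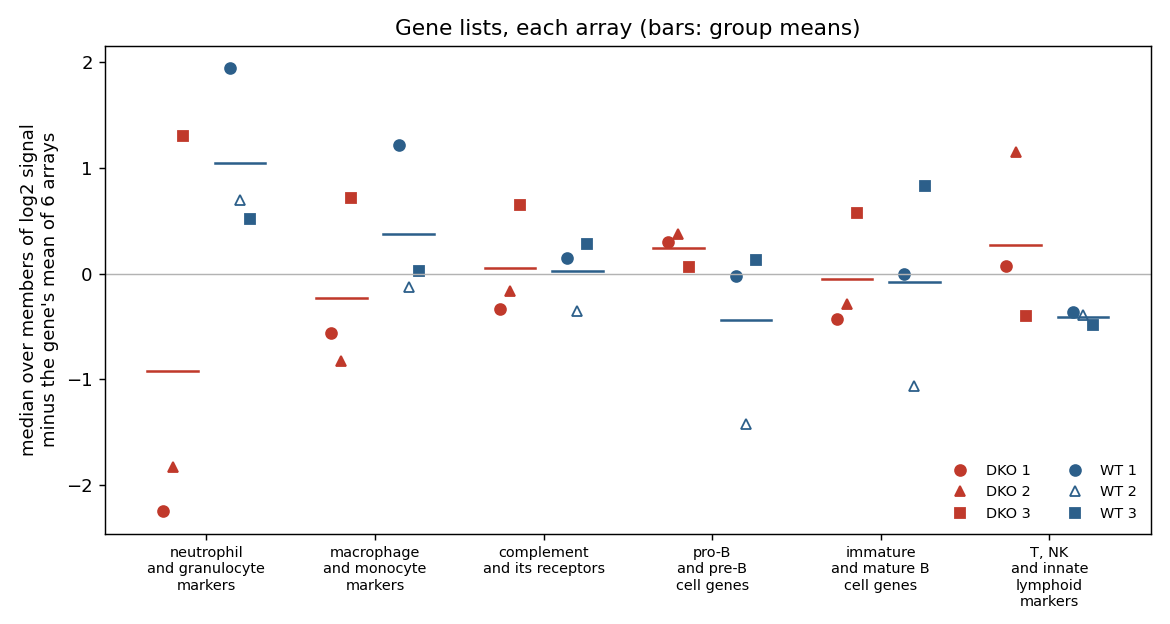
Median over the members of 6 gene lists (horizontal axis) of log2 signal minus each gene's mean over the 6 arrays (vertical axis). Points are single arrays (DKO red, WT blue, WT 2 open) and bars are group means. For granulocyte markers DKO 1 and DKO 2 lie at -2.25 and -1.82, and DKO 3 lies at 1.30, between WT 1 (1.94) and WT 2 (0.69).

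Target genes of p53 were shifted to higher signal (camera adjusted p = 0.00833, and adjusted p = 0.763 with an estimated correlation), with all 15 on the higher side, among them Sesn2 (0.92) and Plk2 (1.42). On WT 2 the median of these genes, each against its mean over the 6 arrays, was -1.29, and DKO 3 (0.08) lay below WT 3 (0.31). Without WT 2 the median log2 difference was 0.39, where it was 0.92 with all 6 arrays, and the camera adjusted p was 0.0407, with an adjusted p of 0.658 with an estimated correlation. Leaving out DKO 2 or WT 1 gave 0.064 and 0.0565. Of 25 proliferation genes, 17 had higher mean signal with all 6 arrays, with a median of 0.31 and a camera direction towards lower signal (adjusted p = 0.433). Mcm5 read -0.47 and Rrm2 -0.54, and other probe sets read 0.43 and 1.12 for Mcm5 and 0.82 and 0.88 for Rrm2, all of which turned negative without WT 2 (-0.60, -0.06, -0.26 and -0.53). Without WT 2, 21 of the 25 genes were lower, with an adjusted p of 3.0e-05 and an adjusted p of 0.658 with an estimated correlation. Markers of T, NK and innate lymphoid cells gave an adjusted p of 0.10 (0.000696 without DKO 3 and 0.0268 without WT 2, and with an estimated correlation 0.464 and 0.658), and Cd3d read 7.48, 8.37 and 4.92 on DKO 1 to 3 and at most 4.84 on the WT arrays, and Klrd1 differed by 1.65. Interferon-stimulated genes gave 0.586 (0.0268 without WT 2, and there 0.658 with an estimated correlation), with Zbp1 at 1.48 and Gbp6 at 3.11 (2.52 without WT 2, 1.93 without DKO 2 and 4.49 without DKO 3). Gbp6 signal was 410 and 1643 on DKO 1 and DKO 2, and on DKO 3 it was 24.5, within the range of the WT arrays (13.6 to 37.8). The remaining lists did not pass camera in the main fit of all 6 arrays or in the fit without WT 2. Their adjusted p values with all 6 arrays were 0.734 for dendritic cell markers (Itgax 1.06, Batf3 1.09), 0.124 for mast cell and basophil markers (Mcpt8 1.51, Gata2 1.03) and 0.0786 for erythroid and megakaryocyte markers (Ppbp -2.03, Pf4 -1.96). Leaving out 1 array gave -3.08 (DKO 3) to -1.37 (DKO 1) for Ppbp and -3.51 (DKO 3) to -1.08 (DKO 1) for Pf4, whose signal on DKO 3 (3950) lay above WT 1 and WT 3. The camera adjusted p values were 0.586 for stromal and endothelial markers (Vcam1 0.64, Fn1 0.80), 0.445 for inflammatory and NF-kB genes (Icam1 1.09, Cxcl2 -1.40), 0.164 for immediate early and heat shock genes (Egr2 0.65, Nr4a1 1.07) and 0.734 for sex-linked genes (Uty 0.60, and Eif2s3y 0.82 with 0.10 without WT 2). Cxcl2 read -2.14 to -0.69 with 1 array left out. Over all settings of the list tests the lowest adjusted p of inflammatory and NF-kB genes was 0.0149. Without WT 2 the camera direction of stromal and endothelial markers turned to higher signal (adjusted p = 0.229). Without DKO 3, mast cell and basophil markers passed with an adjusted p of 3.6e-07 (0.19 with an estimated correlation) and a median of 1.80, with per-array medians against the mean of 6 arrays of 1.33, 1.17 and -0.89 on DKO 1 to 3 and -0.18, -0.51 and -0.93 on WT 1 to 3. Immediate early and heat shock genes passed without DKO 3 (0.0105), and erythroid and megakaryocyte markers without DKO 1 (0.0336), DKO 2 (0.0396) or DKO 3 (0.0176). With an estimated correlation these were 0.464 for immediate early and heat shock genes and 0.63, 0.571 and 0.264 for erythroid and megakaryocyte markers. In total camera called 6 of 21 lists with all 6 arrays and 8 without WT 2, of which 4 were shared with the same direction, and 0 with an estimated correlation in either case or without DKO 1, DKO 2 or DKO 3. Among the lists of this paragraph 0 members passed over all probe sets and 0 when adjusted over the list alone.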

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

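The count of 2 called probe sets was 2 with no filter, without a trend in the variances and with a log2 difference of at least 1, and 3 with a pseudocount of 64. It was 0 with quantile normalization, with centring over the tested probe sets, with a pseudocount of 1 and with no centring, and 1 with the stricter filter and with robust variances. Leaving out 1 array gave 0 to 5. Array weights gave 8129 probe sets and 3794 genes, with weights that did not converge (30.8 for WT 1 and 0.0526 for WT 2). Without WT 2 and with a 2nd array left out, choices made after seeing the data, the count was 4 without DKO 1, 0 without DKO 2, WT 1 or WT 3, and 891 without DKO 3, and it was 5 without WT 2 with quantile normalization. The count of 1 gene was 0 in the settings that gave 0 probe sets, 578 without WT 2 and DKO 3, and 0 to 1 with 1 array left out. With the replicate number as a block, the replicate block, 0 probe sets and 0 genes were called, and the adjusted p of immature and mature B cell genes was 0.0221. The labels do not say that the numbers pair the arrays. Deviations from the group mean correlated at -0.15, -0.0019 and 0.33 for same-numbered arrays. These values do not decide, because WT 2 enters the WT mean. Its deviations correlated at -0.87 with those of WT 1 and at -0.91 with those of WT 3. Cry1 passed at -1.87 with array weights and at -1.64 with WT 2 and DKO 3 left out. The median of all tested probe sets moved from 0.21 to -0.02 with quantile normalization and to -0.10 with no centring. Of 75 named genes 12 turned sign at least once, in 71 of 1689 values, and 93 values gained a call and 13 lost one. Of 650 list values, 481 kept direction and side of the threshold, 76 lost a call, 48 gained one and 45 turned direction. The cause of these changes was not tested. Hlf read 0.0728 with WT 2 and DKO 3 left out and 0.13 with WT 2 and WT 1 left out. Wee1 read -0.088 with quantile normalization, -0.30 with array weights, -0.24 with quantile normalization without WT 2, -0.0954 with WT 2 and DKO 1 left out, -0.16 with WT 2 and DKO 2 left out, -0.49 with WT 2 and DKO 3 left out, -0.33 with WT 2 and WT 1 left out and -0.17 with WT 2 and WT 3 left out, and -0.25 to 0.79 with 1 array left out. Usp2 read -0.35 with quantile normalization, -0.23 with centring over tested probe sets, -0.0124 with a pseudocount of 64, -0.25 with no centring, -0.0638 with WT 2 and DKO 1 left out and -0.042 with WT 2 and WT 1 left out, and -0.044 to 0.17 with 1 array left out. Clock read -0.0501 with array weights, -0.0814 with quantile normalization without WT 2, -0.15 with WT 2 and DKO 2 left out, -0.15 with WT 2 and DKO 3 left out, -0.00488 with WT 2 and WT 1 left out and -0.13 with WT 2 and WT 3 left out, and -0.0654 to 1.84 with 1 array left out. Nfil3 read -0.78 to 0.14 with 1 array left out. Rora read 0.22 with array weights, 0.12 with quantile normalization without WT 2, 0.20 with WT 2 and DKO 2 left out, 0.32 with WT 2 and DKO 3 left out, 0.14 with WT 2 and WT 1 left out and 0.20 with WT 2 and WT 3 left out, and -0.28 to 0.17 with 1 array left out. Csnk1d read 0.13 with array weights, 0.10 with quantile normalization without WT 2, 0.0494 with WT 2 and DKO 1 left out, 0.14 with WT 2 and DKO 2 left out, 0.13 with WT 2 and DKO 3 left out, 0.0692 with WT 2 and WT 1 left out and 0.14 with WT 2 and WT 3 left out, and -0.71 to 0.11 with 1 array left out. Csnk1e read -0.63 with array weights, -0.35 with quantile normalization without WT 2, -0.44 with WT 2 and DKO 1 left out, -0.27 with WT 2 and DKO 2 left out, -0.32 with WT 2 and DKO 3 left out, -0.0848 with WT 2 and WT 1 left out and -0.60 with WT 2 and WT 3 left out, and -0.34 to 1.29 with 1 array left out. Timeless read -0.17 with quantile normalization, -0.40 with array weights, -0.0116 with no centring, -0.36 with quantile normalization without WT 2, -0.24 with WT 2 and DKO 1 left out, -0.22 with WT 2 and DKO 2 left out, -0.60 with WT 2 and DKO 3 left out, -0.49 with WT 2 and WT 1 left out and -0.22 with WT 2 and WT 3 left out, and -0.35 to 0.75 with 1 array left out. C1qa read -1.03 with array weights, -0.71 with quantile normalization without WT 2, -1.11 with WT 2 and DKO 2 left out, -1.19 with WT 2 and DKO 3 left out, -0.0226 with WT 2 and WT 1 left out and -1.32 with WT 2 and WT 3 left out, and -0.67 to 1.74 with 1 array left out. Cxcl2 read 0.21 with WT 2 and WT 1 left out. Eif2s3y read -0.0174 with WT 2 and DKO 2 left out and -0.0428 with WT 2 and WT 1 left out. For E-box clock genes adjusted p was 0.365 with an estimated correlation, 0.658 with an estimated correlation without WT 2, 0.0858 with fry without WT 2, 0.557 with an estimated correlation without DKO 1, 0.571 with an estimated correlation without DKO 2 and 0.225 with an estimated correlation without DKO 3. For RORE and other clock genes adjusted p was 0.939 with quantile normalization, 0.988 with the stricter filter and 0.708 with fry. For complement and its receptors adjusted p was 0.209 with quantile normalization, 0.14 with centring over tested probe sets, 0.0647 with a pseudocount of 64, 0.107 with no filter, 0.151 with no centring, 0.392 with quantile normalization without WT 2, 0.88 with WT 2 and DKO 1 left out, 0.261 with WT 2 and DKO 2 left out, 0.236 with WT 2 and DKO 3 left out, 0.717 with WT 2 and WT 1 left out, 0.354 with WT 2 and WT 3 left out, 0.452 with an estimated correlation, 0.692 with fry, 0.133 with ranks, 0.658 with an estimated correlation without WT 2, 0.923 with fry without WT 2, 0.63 with an estimated correlation without DKO 1, 0.571 with an estimated correlation without DKO 2 and 0.225 with an estimated correlation without DKO 3, and 0.00375 to 0.398 with 1 array left out. For pro-B and pre-B cell genes adjusted p was 0.0166 with quantile normalization and 0.000448 with WT 2 and DKO 3 left out, and 0.0112 to 0.412 with 1 array left out. For immature and mature B cell genes adjusted p was 0.0141 with the stricter filter, 0.0221 with the replicate block, 0.0262 with quantile normalization without WT 2, 0.000448 with WT 2 and DKO 3 left out and 0.000613 with WT 2 and WT 1 left out, and 0.000364 to 0.524 with 1 array left out. For B cell receptor signalling adjusted p was 0.349 with quantile normalization without WT 2, 0.902 with WT 2 and DKO 1 left out, 0.281 with WT 2 and DKO 2 left out, 0.243 with WT 2 and DKO 3 left out, 0.0606 with WT 2 and WT 1 left out, 0.658 with an estimated correlation without WT 2, 0.774 with fry without WT 2 and 0.924 with an estimated correlation without DKO 3, and 0.229 to 0.815 with 1 array left out. For IL-7 receptor and STAT5 genes adjusted p was 0.987 with WT 2 and WT 1 left out. For dendritic cell markers adjusted p was 0.986 with an estimated correlation without DKO 2 and 0.883 with an estimated correlation without DKO 3, and 0.607 to 0.986 with 1 array left out. For stromal and endothelial markers adjusted p was 0.721 with quantile normalization, 0.759 with the stricter filter, 0.273 with quantile normalization without WT 2, 0.285 with WT 2 and DKO 1 left out, 0.722 with WT 2 and DKO 2 left out, 0.232 with WT 2 and DKO 3 left out, 0.143 with WT 2 and WT 1 left out, 0.603 with WT 2 and WT 3 left out, 0.676 with fry, 0.658 with an estimated correlation without WT 2, 0.672 with fry without WT 2 and 0.883 with an estimated correlation without DKO 3, and 0.229 to 0.835 with 1 array left out. For proliferation genes adjusted p was 0.782 with fry and 0.986 with an estimated correlation without DKO 2, and 3.0e-05 to 0.986 with 1 array left out. For interferon-stimulated genes adjusted p was 0.0268 to 0.986 with 1 array left out. For inflammatory and NF-kB genes adjusted p was 0.728 with WT 2 and DKO 3 left out, 0.143 with WT 2 and WT 1 left out, 0.738 with fry and 0.997 with fry without WT 2, and 0.164 to 0.983 with 1 array left out. For immediate early and heat shock genes adjusted p was 0.55 with WT 2 and WT 3 left out. For sex-linked genes adjusted p was 0.815 with WT 2 and WT 1 left out, and 0.467 to 0.986 with 1 array left out.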

Other observations

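All tests of explanations below were chosen after the results were seen, except the count of gene lists over splits of the arrays, which was set before that count was made. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2 probe sets and the highest of the others 0, and 1 of the 10 splits, the real one, reached that number. It called 1 gene and the highest of the others 0, and again 1 split reached that number. It called 6 gene lists and the highest of the others 10, and 5 of the 10 splits called at least 6. The E-box clock list had a camera adjusted p of 4.4e-06 in the real split and of at least 0.0638 in the others. At an unadjusted p under 0.05 the real split had 844 probe sets and the split of DKO 1, DKO 2 and WT 2 against the rest had 2679, which points to a structure of the samples other than genotype. These arrays also had the highest Actb 3' to 5' ratios (2.05, 1.71 and 824, and 1.47 to 1.63 on the rest). For Gapdh, DKO 2 had the lowest ratio (0.838). Whether RNA quality bears on this split was not tested.

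WT 2 stood apart from the other 5 arrays. A single scaling factor from the authors' processing is argued against as the whole cause. A factor cancels in a ratio, and the log2 3' to 5' ratio of Actb on WT 2 exceeded the highest of the others by 8.65. A larger factor on WT 2 as part of the cause stays open. Bacterial controls there were 4.52 times their mean on the other arrays. The highest signal was 141224 on WT 2 and 36075 to 40686 on the others. Degraded RNA or truncated cDNA may account for how WT 2 stood apart, since the Actb ratio was 824 where the others stayed under 2.05. The extra spread of WT 2 alone is argued against as the reason for the few calls, as only 5 probe sets passed without it. No biological explanation of WT 2 was tested.

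Granulocyte markers were low in DKO 1 and DKO 2 and not in DKO 3. A difference shared by the 3 DKO arrays is argued against, since 0 of 16 markers lay below every WT array in DKO 3. For a mislabelled wild type sample in the place of DKO 3 the measures divide, and the E-box clock genes argue against it. On DKO 3, 9 of 13 E-box clock genes lay above every WT array, next to 10 on DKO 1 and 9 on DKO 2. Of the 100 genes with the smallest p in a fit without DKO 3, by representative probe set, 28 had DKO 3 beyond every WT array on the side of DKO 1 and DKO 2. This count does not decide, since WT 1, WT 2 and WT 3, each held out in the same way, gave 64, 32 and 63 against the other 2 WT arrays. The largest distances among these genes go against a wild type sample, at 6.25 log2 units beyond every WT array for Igha, 5.84 for Ccnb1ip1 and 3.50 for Gdpd3, where a held-out WT array reached at most 3.07. The correlation across probe sets goes with it, as DKO 3 correlated with WT 3 (0.984) more closely than with DKO 1 (0.936) or DKO 2 (0.952). Different shares of myeloid cells between samples could account for the pattern, the 0 of 16 in DKO 3 included, and this was not tested further, because arrays grouped by these markers would be compared on the same outcome. Dntt, Cd22 and Cd3d values divided the DKO arrays in the same way, and whether they share a cause with the granulocyte markers was not tested.

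Genes with the smallest p lay close together on chromosomes, most of all on chromosome 14, which held 22 of the 100 genes with the smallest p where 3.47 were due, each gene ranked by the probe set with its smallest p and immunoglobulin genes left out. They formed 59 pairs within 25 genes (random median 19, permutation p = 1e-04, the smallest 10000 permutations can give), against 33 in the highest of the other 9 splits, and the first statistic gave 47 genes with another one near (random median 32, permutation p = 0.0071) against 41. The pairs fell to 35 without DKO 3 (permutation p = 0.0013), with 11 genes on chromosome 14 where the highest other chromosome held 10, and to 34 without WT 3 (permutation p = 0.0020), with 16 on chromosome 14. With any 1 of the other 4 arrays left out they were 49 to 69. Other splits reached a permutation p of 0.0040 (33 pairs) and 0.022 (29 pairs), so a small permutation p alone does not point to genotype. The first statistic had a permutation p above 0.05 without WT 1 (0.075) and without WT 3 (0.28). Over 9 combinations of 50, 100 or 200 genes and of 10, 25 or 50 genes of distance, the pairs kept the smallest p that 2000 permutations can give, and the first statistic ranged up to p = 0.842. DNA next to the targeted genes is argued against, since Cry1 and Cry2 lie on chromosomes 10 and 2. The genes flanking them held 1 of the 100 (3 without WT 2, 1 without WT 3, and 0 with any of the other 4 arrays left out). Probes that bind another sequence less well are argued against as the whole cause, since 9 of the 22 were higher in DKO. Without WT 2 fewer of the 22 then on chromosome 14 were higher, namely Nr1d2, Gch1, Ccnb1ip1, Mtmr9, Nkx2-6 and Sorbs3, which weakens this argument. A chromosome segment of other strain origin in the knockout line may account for the pairs on chromosome 14, though the count rests in part on DKO 3 and WT 3. Pairs also lay on other chromosomes, among them 4, 7 and 15, but random draws gave a median of 19 pairs over all chromosomes. Whether the pairs outside chromosome 14 exceed what chance gives was not tested. Neighbours that vary together between samples cannot be told apart from such a segment, because 10 splits are too few, although the highest number on any 1 chromosome in the other splits was 13.

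Named after their values were seen, the genes on chromosome 14 included Psmd6 (-4.22 at 1 probe set, and 0.82 at another, which read -0.10 without WT 2), Ccnb1ip1 (4.21), Rem2 (-3.00), Gmfb (-2.10) and the clock gene Nr1d2 (3.08). A stretch of chromosome 4 held Tnfrsf14 (3.12), Ssu72 (2.16), Mxra8 (1.73) and B3galt6 (-2.45). Of the 22 genes on chromosome 14, 13 had another tested probe set, and for 5 of them another probe set moved in the same direction by at least 50% as much, next to 18 of 46 for the other genes of the 100, so this share did not set chromosome 14 apart.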
